A study of Mus musculus with 4 samples.

How the data were processed

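The study sequenced polyadenylated RNA of muscle stem cells from 4 libraries, 2 labelled YFP and 2 labelled DEK. Per the labels' protocols, mice were perfused with paraformaldehyde, muscle was digested with collagenase, fixed cells were sorted by flow cytometry, RNA was extracted with a kit for fixed tissue, and cDNA was made with a low-input template-switching kit before shearing and paired-end sequencing. The sort gate, the sex of the mice, the time of day and the number of animals behind each library are not stated. Per the submitters' processing notes, the authors used STAR 2.5.3a, StringTie 1.3.3 and R 3.4.1 on build mm9; settings, annotation and filters are not stated. The deposited table holds 1 value per gene symbol and library, read here as FPKM made by the authors with StringTie (scaled by transcript length and library size). That unit is inferred: the values are not whole, the column totals differ and are not those of TPM over a full annotation, and 89.1% of values above 0 in the column examined carry over 6 decimals. TPM cannot be excluded. All 4 value columns were used and 0 were left out. The table gives no coordinates or identifiers besides symbols, and no coordinates were taken from another build. Symbols that look like dates, 27 in all, were kept as written and match no list.

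Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Genes at 1 FPKM or more in at least 2 libraries were tested (12179 genes, while 12149 were not). A gene under 1 FPKM in both libraries of a group was thus tested only where both values of the other group reached 1 FPKM. DEK was compared with YFP by a linear model with an empirical Bayes variance trend and no covariates, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. Age, reporter, locus and genotype go with the group, so no term for them could be fitted. A fold change on this scale understates genes with low values, and a gene listed at 0 has a fitted change that depends on the added 1, so none is given for it; list medians include such genes. Depth per library is unknown, since the table gives no counts, and no intervals or detection limits are given. The labels do not say whether replicates are separate animals, so the p-values measure the spread between these libraries.

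Named genes were chosen by rule: Dek; the 15 genes with the largest positive and the 15 with the largest negative log2 fold change among called genes without overlap between groups and with a mean of at least 5 FPKM in the higher group, skipping predicted models (400 and 318 genes were eligible; 0 were skipped); and up to 4 members with the smallest p in each list. Not every gene that the rule takes is described. In the report, genes outside the rule are marked as chosen after their values were seen, except Rn45s; all genes outside it in the observations were chosen in that way, or belong to sets chosen later. The test, the rule, the lists and the alternatives, except those named as later, were fixed before the data were examined.

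The 30 lists were quiescence-associated satellite cell genes, myogenic commitment and differentiation genes, immediate early and dissociation response genes, cell cycle genes, splicing factor genes, glycolysis genes, fatty acid oxidation genes, translation factor genes, unfolded protein response genes, p53 target and senescence genes, interferon response genes, extracellular matrix genes, Notch pathway genes, chromatin and histone chaperone genes, nuclear export and 3' end processing genes, markers of mature myofibres, fibro-adipogenic progenitors, endothelial cells, pericytes and smooth muscle, macrophages and monocytes, other leukocytes, erythroid cells, Schwann cells and tenocytes, sex-linked genes, age-shift genes, cytosolic ribosomal protein genes, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes and replication-dependent histone genes. They were written from general knowledge and some share members. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 29 lists; list means and medians are of log2 fold changes. Member counts are given over all genes and adjusted over the list alone.

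Alternatives were each library left out in turn on the same genes, where the lone library of a group is taken to vary like the other group; the replicate number as a block; an added value of 0.1 or 5; no low filter, or 5 FPKM in 2 libraries; TMM factors (trims of 30 and 5%) or quantile normalization; limma without the trend or with robust estimation; an adjusted p under 0.1, or a 2-fold minimum; camera with an estimated correlation; fry; and 10000 random lists matched in 20 bins of mean expression. Chosen after seeing the data were the removal of Rn45s with rescaling, the low filter applied to the 3 remaining libraries when 1 is left out, and 4 further gene sets. Alternatives that need counts, foreseen at the outset, were not run because the table holds no counts. Permutation tests of list labels used 100000 draws. The limma test was checked on simulated data with 200 changed genes of 12179 in 20 draws: it recovered 16.7, 92.7, 99.5 and 99.8% of changes of 1, 2, 3 and 4 on the log2 scale, and 4.03% of its calls were false. The simulated genes were independent, had the kind of spread that the test assumes and shared no library effect. That share is therefore not the error rate of the calls in the real data.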

Results

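Polyadenylated RNA was sequenced from muscle stem cells (satellite cells) that were fixed inside the mouse by paraformaldehyde perfusion and then sorted from skeletal muscle. The 4 libraries fell into 2 groups of 2 replicates. The YFP group carried the tamoxifen-inducible Pax7CreERT2 driver with a YFP reporter at ROSA26, at 7 months of age. The DEK group carried the same driver with a DEK-EGFP transgene at H11, at 4.5 months of age. Age, reporter and locus went with the group in all 4 libraries, so every difference between DEK and YFP holds for that combination. The table held 24328 gene symbols, of which 5999 were at 0 in all libraries and 12179 reached 1 FPKM in at least 2 libraries and were tested. Column totals were 541183 and 541320 FPKM in YFP replicates 1 and 2, and 545123 and 543223 FPKM in DEK replicates 1 and 2. The number of genes at 1 FPKM or more was 11733, 11669, 11889 and 12000 in the same order. The ribosomal RNA precursor Rn45s took 11.8% and 15.7% of the total in YFP and 5.15% and 5.55% in DEK. Read depth is unknown because the values are not counts.

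The comparison of DEK with YFP asked what raising Dek, a DNA-binding chromatin protein, does to the RNA of quiescent muscle stem cells. Dek itself was at 508 ± 5.24 FPKM in YFP and 2418 ± 1101 FPKM in DEK (SD, n = 2 each), with 3196 in DEK replicate 1 and 1639.5 in DEK replicate 2. Its log2 fold change was 2.17 (SE 0.31, limma adjusted p = 0.0195). The species and length of the transgene's cDNA are not given, so whether the values in DEK count it in full is unknown. By limma 11 of 40 immediate early and dissociation response genes, 14 of 19 endothelial markers and 8 of 12 macrophage markers rose in DEK. Falling were 10 of 25 myogenic genes, among them Myog and Actc1, 11 of 46 cell cycle genes and 9 of 32 matrix genes, among them Sparc. Each of these lists passed camera at a preset correlation of 0.01 and lost that call with an estimated correlation (adjusted p = 0.626 or 0.650). The latter setting tests on the residual degrees of freedom of only 4 libraries and passed 0 of 29 lists. Its loss of a call therefore does not show that correlated genes made the call. In total 948 genes passed limma at an adjusted p under 0.05, 7.78% of those tested, with 557 higher and 391 lower in DEK. At 2-fold or more, 412 were higher and 260 lower.

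For each of the 948 genes both DEK values lay on the same side of both YFP values, as did 60.9% of all tested genes, where chance gives 33.3%. The smallest exact permutation p that 2 against 2 libraries allow is 0.333. Across genes, Pearson's r of the log2 values was 0.978 between the YFP libraries, 0.975 between the DEK libraries and 0.913 to 0.944 across groups; genes are not independent replicates. The first principal component held 73.2% of the variance and split DEK from YFP. Higher genes made up 58.8% of the calls, 52.6% after TMM scaling, 45.4% after quantile normalization and 42.8% with Rn45s removed, which moved the median log2 fold change of all genes from 0.05 to -0.07. Without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, limma called 115, 69, 0 and 184 genes, with 3018, 2330, 2215 and 2896 at an unadjusted p under 0.05 against 3545 with all libraries. With the low filter applied instead to the 3 remaining libraries (refiltered, a setting chosen after the data were seen), the numbers were 168, 83, 302 and 780, of which 144, 79, 248 and 429 were among the 948. The Dek call was lost without YFP replicate 1 (adjusted p = 0.109), YFP replicate 2 (0.150) and DEK replicate 1 (0.0798, log2 fold change 1.69; 0.00361 refiltered), held without DEK replicate 2 (0.0350, log2 fold change 2.65), and was lost with no low filter (0.0863). Over all alternatives the adjusted p of Dek ran from 0.000209 to 0.150. Kdm1b, annotated on the other strand with its end over that of Dek and chosen after its values were seen, had a log2 fold change of 0.43 (adjusted p = 0.163).

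The largest rises were in the inducible heat shock genes Hspa1a and Hspa1b. Hspa1a stood at 4.16 ± 1.06 FPKM in YFP and at 3419 and 654 FPKM in DEK replicates 1 and 2 (log2 fold change 8.20, SE 0.71, adjusted p = 0.00506). Hspa1b, a near-identical copy that reads cannot always be told from, had a log2 fold change of 7.21 (SE 0.65, adjusted p = 0.00542). Idi1, an enzyme of isoprenoid synthesis, went from 0.559 ± 0.0891 to 30.5 ± 9.21 FPKM (log2 fold change 4.31, SE 0.25, adjusted p = 0.0031). The immediate early genes Nr4a1 and Fosb had log2 fold changes of 4.999 (SE 0.36) and 3.99 (SE 0.30), and Ier2 had 3.87 (SE 0.58). The stress genes Gadd45b and Hspb1 had 4.05 (SE 0.83, adjusted p = 0.0423) and 3.88 (SE 0.67, adjusted p = 0.0298). Genes best known from other cell types were among the rises. The endothelial phosphatase Ptprb was listed at 0 in both YFP libraries and stood at 34.9 and 23.9 FPKM in DEK (adjusted p = 0.00289). Log2 fold changes were 4.90 for the lipid carrier Fabp4, 4.43 for Ly6c1, 4.32 for the water channel Aqp1 (each with adjusted p = 0.0031) and 4.48 for the antigen presentation gene Cd74 (adjusted p = 0.0287). The alpha globin gene Hba-a1 was at 0.0627 and 0 FPKM in YFP and at 11.1 and 111 FPKM in DEK (adjusted p = 0.0346); its copy Hba-a2 is close to it in sequence. With a library omitted, limma called 9, 8, 0 and 13 of the 15 genes with the largest rises without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, and all 15 had an unadjusted p under 0.05 each time. Refiltered, 11, 9, 10 and 11 were called, and Ptprb, Ly6c1, Idi1 and Hba-a1 missed the filter when a DEK library was left out.

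The deepest falls included genes of muscle differentiation. Cardiac alpha actin Actc1, a gene of developing muscle, went from 108 ± 21.4 FPKM in YFP to 3.58 ± 3.42 FPKM in DEK (log2 fold change -4.80, SE 0.52, adjusted p = 0.00931). The myogenic regulator Myog went from 111 ± 17.98 to 8.06 ± 7.95 FPKM (log2 fold change -3.97, SE 0.63, adjusted p = 0.0242). Tmem8c, which drives myoblast fusion, went from 68.7 ± 11.9 to 5.30 ± 5.22 FPKM (log2 fold change -3.76, SE 0.59, adjusted p = 0.0234). The cell cycle inhibitor Cdkn1c fell with a log2 fold change of -3.30 (SE 0.64, adjusted p = 0.0382) and the spindle gene Aspm with -3.19 (SE 0.64, adjusted p = 0.0409). Pthlh, a secreted hormone-like peptide, went from 27.2 ± 2.51 to 0.185 ± 0.00895 FPKM (adjusted p = 0.00289), and the oxytocin receptor Oxtr from 7.52 ± 0.823 to 0.0824 ± 0.0755 FPKM (adjusted p = 0.00353). The arginase Arg2 had a log2 fold change of -2.81 (SE 0.16), the metalloprotease Adam12 -2.67 (SE 0.19), the glucocorticoid-induced chaperone Fkbp5 -2.63 (SE 0.18) and Flrt1 -2.63 (SE 0.26). The keratin gene Krt76 stood at 6.42 and 7.14 FPKM in YFP and was listed at 0 in both DEK libraries, and the kallikrein Klk1 stood at 6.2002 and 5.08 FPKM in YFP and at 0 and 0.166 FPKM in DEK. Rpl37rt had a log2 fold change of -4.78 (SE 0.24) while Rpl37, its near-identical parent, had -0.21 (adjusted p = 0.524), and Hist1h2ao had -3.74 (SE 0.28) while its copy Hist1h2ap had -0.58 (adjusted p = 0.492). Reads shared between such copies make both falls uncertain; Rpl37 and Hist1h2ap were chosen after their values were seen. With the libraries left out in the same order as for the rises, limma called 9, 9, 0 and 14 of these 15 genes, again with all 15 at an unadjusted p under 0.05. Refiltered, 5, 4, 15 and 15 were called, and Krt76, Oxtr, Klk1, Pthlh and Hist1h2ao missed the filter when a YFP library was left out.

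**Figure D1:**
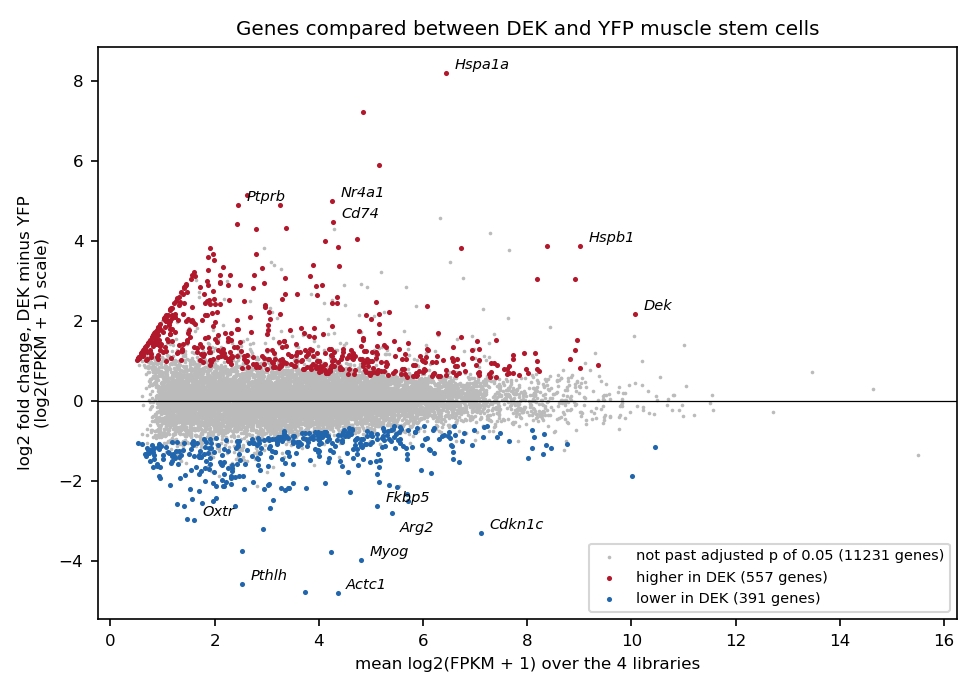
Each point is a tested gene, with its mean log2(FPKM + 1) over the 4 libraries on the x axis and its log2 fold change, DEK minus YFP, on the y axis; genes past an adjusted p under 0.05 are coloured. The 557 higher genes reach 8.20 at Hspa1a and the 391 lower genes -4.80 at Actc1.

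Gene lists were tested with camera, in limma, at a preset correlation. Of 30 lists 29 held tested genes and 13 passed, 9 upward and 4 downward. With an estimated correlation 0 lists passed camera, with 1 at an unadjusted p under 0.05, and the smallest adjusted p was 0.626. The macrophage list had an estimated correlation of -0.0329, below the preset 0.01, yet its unadjusted camera p went from 1.46e-09 to 0.0237. In the interferon list, at -0.0212, it went from 0.0302 to 0.136. A higher correlation is thus argued against as the cause for these lists. With an estimated correlation camera tests on the residual degrees of freedom of the 4 libraries. With a preset one it tests on those of all tested genes, and this drop alone raises the p of both lists. The other lists that passed had estimated correlations above the preset one, so there the drop and the correlation act together. With fry, which asks whether a list moves on balance without comparing it with other genes, 2 passed, the endothelial and macrophage markers.

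Genes of commitment and differentiation are switched on as satellite cells leave quiescence for the muscle lineage. Of 25 measured members of the myogenic list, 10 fell and 0 rose by limma, against 3 at an unadjusted p under 0.05 in the upward direction; adjusted over the list alone, 12 fell and 3 rose. The list median was -0.73 (camera adjusted p = 0.000212; adjusted p = 0.626 with an estimated correlation). It was -0.48 without DEK replicate 2, -0.52 without DEK replicate 1, -0.72 without YFP replicate 1, -0.60 without YFP replicate 2 and -0.46 with an added value of 5. Refiltered without YFP replicate 1 the median was -0.21. With a YFP library left out that filter tested only 21 of the 25 members, since members low in DEK miss it, and 43 of the 46 cell cycle members. Refiltered values without a YFP library thus leave out such members and do not test the whole lists. Besides Actc1, the acetylcholine receptor subunits Chrnd and Chrng fell with log2 fold changes of -2.54 (SE 0.20) and -2.19 (SE 0.30), and the perinatal myosin Myh8 went from 2.58 and 1.96 FPKM to 0 and 0.101 FPKM. In cell cycle genes 11 of 46 fell and 1 rose, and 19 fell and 2 rose adjusted over the list alone (median -0.58, -0.36 with an added value of 5, camera adjusted p = 1.31e-06; adjusted p = 0.626 with an estimated correlation). The proliferation marker Mki67 went from 8.50 ± 0.0119 to 1.36 ± 1.25 FPKM (log2 fold change -2.12, SE 0.38, adjusted p = 0.0322). Cyclin Ccna2 and the tubulin regulator Stmn1 fell with log2 fold changes of -1.59 (SE 0.23) and -1.37 (SE 0.17), while cyclin Ccnd2 rose from 0.245 ± 0.128 to 2.02 ± 0.357 FPKM. In the same DEK libraries the endothelial marker list stood at a median log2 fold change of 1.73 and the dissociation response list at 2.20. Without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, limma called 1, 1, 0 and 4 myogenic genes lower, with 11, 13, 13 and 13 at an unadjusted p under 0.05. In the same order limma called 0, 0, 0 and 2 cell cycle genes lower, with 20, 21, 17 and 25 at an unadjusted p under 0.05. Refiltered, the limma calls were 0, 0, 6 and 7 myogenic genes lower, with 7, 9, 13 and 14 at an unadjusted p under 0.05. For cell cycle genes they were 0, 0, 3 and 13 lower, with 17, 18, 18 and 25 at an unadjusted p under 0.05 by limma.

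Quiescence-associated genes, by contrast, went in both directions. Of 37 members 2 rose and 5 fell, and 7 rose and 6 fell adjusted over the list alone. The list median was 0.03, the mean -0.08 and the direction of the test down (camera adjusted p = 0.760; adjusted p = 0.905 with an estimated correlation), and the median turned to -0.11 with Rn45s removed. Col5a3, a fibrillar collagen chain, fell from 134 ± 9.41 to 62.5 ± 11.9 FPKM, and the cell cycle inhibitor Cdkn1b and the membrane protein Tenm4 fell with log2 fold changes of -1.03 (SE 0.19) and -0.83 (SE 0.16). Chrdl2, a secreted antagonist of bone morphogenetic proteins, rose with 1.01 (SE 0.18). Among satellite cell transcription factors chosen after their values were seen, log2 fold changes were 0.57 for Pax7 (adjusted p = 0.159), -0.46 for Myod1 (adjusted p = 0.108) and -0.35 for Myf5 (adjusted p = 0.190). Without YFP replicate 1, YFP replicate 2 and DEK replicate 1, limma called 0 members of the list, with 4, 3 and 13 higher and 5, 6 and 7 lower at an unadjusted p under 0.05, and without DEK replicate 2 it called 2 lower. Refiltered, it called 4 higher and 3 lower without DEK replicate 1, 4 higher and 5 lower without DEK replicate 2 and 0 without a YFP library, with 4 and 3 higher and 6 lower each time at an unadjusted p under 0.05.

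Immediate early and dissociation response genes switch on within minutes of stress or tissue digestion. Here the mice were perfused with paraformaldehyde before the muscle was digested. A response to digestion would thus need incomplete fixation, which was not measured. Of 40 measured members 11 rose and 1 fell, and 23 rose and 1 fell adjusted over the list alone. The list median was 2.20 (camera adjusted p = 1.41e-08; adjusted p = 0.650 with an estimated correlation). Against the YFP mean the list median was 3.20 in DEK replicate 1 and 1.11 in DEK replicate 2. Egr1, chosen after its values were seen, stood at 167 ± 8.19 FPKM in YFP and at 2130 and 916 FPKM in DEK replicates 1 and 2 (log2 fold change 3.06, SE 0.38, adjusted p = 0.0128). Klf6, the member that fell and also chosen after its values were seen, had -0.90 (SE 0.15, adjusted p = 0.0278). The members called higher by limma numbered 2, 1, 0 and 26 without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, with 17, 15, 24 and 35 higher at an unadjusted p under 0.05; refiltered, they numbered 4, 2, 19 and 26. In unfolded protein response genes 1 of 22 rose and 0 fell, the endoplasmic reticulum chaperone Calr (log2 fold change 0.71, SE 0.15, adjusted p = 0.0422), and 0 passed adjusted over the list alone, with 10 higher at an unadjusted p under 0.05. That list had a median of 0.39 (camera adjusted p = 0.0581) and passed without DEK replicate 2 (adjusted p = 0.000691, range over alternatives 0.000123 to 0.650). Without DEK replicate 2 limma called 4 members higher, 6 refiltered, and 0 without each of the others on the same genes, with 4, 3 and 7 at an unadjusted p under 0.05. Pdia3, Sdf2l1 and Hspa5 had log2 fold changes of 0.59, 0.76 and 1.84 that did not pass (adjusted p = 0.0566, 0.0908 and 0.0950).

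In p53 target and senescence genes 4 of 18 fell and 0 rose, against 4 higher at an unadjusted p under 0.05, and 6 fell and 3 rose adjusted over the list alone. The median was -0.22 (-0.03 without DEK replicate 2), the mean 0.14 and the direction of the test down (camera adjusted p = 0.112). Zmat3, an RNA-binding p53 target, went from 36.9 ± 1.72 to 16.7 ± 0.0831 FPKM (log2 fold change -1.10, SE 0.14), and Trp53inp1, Phlda3 and Perp fell with log2 fold changes of -1.21 (SE 0.18), -0.94 (SE 0.15) and -0.91 (SE 0.18). The list passed camera downward without DEK replicate 1 (adjusted p = 0.0348) and at 5 FPKM or more (0.0114), in a range over alternatives of 0.0114 to 0.848. Without YFP replicate 1, YFP replicate 2 and DEK replicate 1 limma called 0 members, with 0, 0 and 3 higher and 6, 5 and 6 lower at an unadjusted p under 0.05, and without DEK replicate 2 it called 3 higher. Refiltered, it called 1 higher and 3 lower without DEK replicate 1, 3 higher and 2 lower without DEK replicate 2 and 0 without a YFP library, with 1 and 0 higher and 6 and 5 lower at an unadjusted p under 0.05.

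Of 19 measured endothelial markers 14 rose and 0 fell by limma, against 15 higher and 0 lower at an unadjusted p under 0.05, and 15 rose adjusted over the list alone (median 1.73, camera adjusted p = 6.15e-12; adjusted p = 0.626 with an estimated correlation; fry adjusted p = 0.0243). The adhesion molecule Pecam1 went from 0.662 ± 0.117 to 13.7 ± 2.24 FPKM (log2 fold change 3.14, SE 0.21, adjusted p = 0.00353), and the tight junction gene Cldn5 from 0.122 and 0 to 13.3 and 10.4 FPKM. Macrophage and monocyte markers rose in 8 of 12 members and fell in 0, with 11 higher and 0 lower at an unadjusted p under 0.05, and 11 rose adjusted over the list alone (median 2.02, camera adjusted p = 1.41e-08; adjusted p = 0.626 with an estimated correlation; fry adjusted p = 0.0243). Only 12 of the 19 macrophage markers in the table passed the low filter. A marker under 1 FPKM in both YFP libraries passed only where both DEK values reached 1 FPKM. In these and the other marker lists such members could only rise, so the counts of members that fell carry that selection. With no low filter the macrophage median was 0.97 (camera adjusted p = 1.84e-09) and the endothelial median 1.72 (camera adjusted p = 2.68e-11). The size of both medians rests on the added 1: with an added value of 0.1 or 5 they were 4.18 and 0.69 for the endothelial and 4.75 and 0.72 for the macrophage list. The growth factor receptor Csf1r went from 0.0977 and 0 to 5.997 and 5.38 FPKM. Listed at 0 in both YFP libraries were Tyrobp, at 4.13 and 5.26 FPKM in DEK, and the complement genes C1qb, at 2.79 and 4.18, and C1qc, at 2.46 and 2.76. Against the YFP mean the endothelial median was 1.82 in DEK replicate 1 and 1.72 in DEK replicate 2, and the macrophage median 1.86 and 2.19. With the libraries left out in the order YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, limma called 10, 5, 0 and 8 endothelial and 4, 3, 0 and 3 macrophage genes higher, with 14 and 9 at an unadjusted p under 0.05 without DEK replicate 1. Refiltered, 10 and 8 endothelial and 5 and 4 macrophage genes were called without YFP replicates 1 and 2. With a DEK library left out that filter kept only 6 endothelial and 4 macrophage members. Members near 0 in YFP then miss it, so that setting does not test either list. Over the other alternatives, the estimated correlation included, camera's adjusted p ran from 3.06e-14 to 0.626 for the endothelial and from 4.67e-11 to 0.626 for the macrophage list.

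Markers of other cell types of muscle went up in part. In the fibro-adipogenic progenitor list 8 of 18 rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone (median 1.07, camera adjusted p = 0.000945, or 0.626 with an estimated correlation). Col3a1, also in the matrix list, was among those that fell (log2 fold change -1.16, SE 0.20). The matrix proteoglycan Dcn went from 13.3 ± 0.935 to 62.0 ± 5.35 FPKM and Ly6a, a surface marker of these cells, from 1.49 ± 0.161 to 16.6 ± 0.00525 FPKM; Smoc2 went from 0.222 and 0 to 10.5 and 16.1 FPKM and Cd248 from 0.0819 and 0 to 3.58 and 2.82 FPKM. In tenocyte markers 6 of 10 rose and 0 fell, with 2 lower at an unadjusted p under 0.05, and 6 rose and 2 fell adjusted over the list alone (median 1.75, 0.93 with no low filter, camera adjusted p = 0.00642; adjusted p = 0.626 with an estimated correlation). The tendon genes Fmod and Thbs4 had log2 fold changes of 3.14 (SE 0.27) and 3.32 (SE 0.32), while Tnmd went from 0.510 and 0 to 7.08 and 8.80 FPKM and Kera from 0.106 and 0 to 3.43 and 3.04 FPKM. Pericyte and smooth muscle markers rose in 5 of 15 and fell in 0, with 2 lower at an unadjusted p under 0.05, and 8 rose and 1 fell adjusted over the list alone (median 0.65, 0.404 without DEK replicate 2, camera adjusted p = 0.0175; adjusted p = 0.626 with an estimated correlation). Steap4 and Rgs5 had log2 fold changes of 1.14 (SE 0.13) and 2.36 (SE 0.32), the smooth muscle myosin Myh11 went from 0.175 and 0 to 3.21 and 3.53 FPKM, and Higd1b, listed at 0 in both YFP libraries, was at 2.40 and 2.06 FPKM. With an added value of 0.1 or 5 the medians were 1.47 and 0.56 for progenitor, 3.07 and 0.66 for tenocyte and 0.69 and 0.301 for pericyte markers. The pericyte call was lost without YFP replicate 1 (adjusted p = 0.0777), without DEK replicate 2 (0.136) and at 5 FPKM or more (0.199), and the progenitor call was lost at 5 FPKM or more (0.109). When YFP replicate 1, YFP replicate 2, DEK replicate 1 or DEK replicate 2 was left out, limma called 3, 3, 0 and 4 progenitor, 4, 4, 0 and 0 tenocyte and 1, 0, 0 and 0 pericyte genes higher, with 10, 11, 10 and 9, with 6 each time and with 7, 7, 8 and 6 at an unadjusted p under 0.05. With a DEK library left out the refiltered setting kept 13 progenitor, 7 tenocyte and 12 pericyte markers and left out members near 0 in YFP, so it is not used for these lists. Over the other alternatives camera's adjusted p reached 0.626 for each of the 3 lists, from 0.000157 for progenitor, 0.00115 for tenocyte and 0.00219 for pericyte markers.

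In blood cell and nerve sheath lists few genes passed, and mature myofibre markers were mixed. In the other leukocyte list 2 of 7 rose, and 5 rose adjusted over the list alone (median 2.44, camera adjusted p = 0.00121; adjusted p = 0.626 with an estimated correlation). The table held 17 of these markers, and the median was 0.74 with no low filter and 1.18 without YFP replicate 1. The actin regulator Coro1a went from 0.629 ± 0.257 to 7.77 ± 0.111 FPKM and Cd52 from 0.541 ± 0.0489 to 11.4 ± 4.36 FPKM, while Ptprc and S100a8 had log2 fold changes of 0.98 and 2.90 that did not pass (adjusted p = 0.0765 and 0.117). In erythroid markers 2 of 5 rose, and 4 rose adjusted over the list alone (median 3.01, camera adjusted p = 0.00595; adjusted p = 0.626 with an estimated correlation). The beta globin gene Hbb-bs had a log2 fold change of 2.99 (SE 0.38, adjusted p = 0.0141); Hba-a2 was at 5.43 and 0 FPKM in YFP and 11.5 and 62.7 in DEK, and Hbb-b2 at 0.203 and 0 in YFP and 1.78 and 27.3 in DEK, and neither passed (adjusted p = 0.0964 and 0.114). The erythroid median against the YFP mean was 2.30 in DEK replicate 1 and 4.69 in DEK replicate 2. In Schwann cell markers 2 of 9 rose, and 6 rose adjusted over the list alone (median 1.05, 0.62 with no low filter, camera adjusted p = 0.00332; adjusted p = 0.626 with an estimated correlation). The myelin gene Mbp had a log2 fold change of 1.79 (SE 0.21); Mag had 1.05 (adjusted p = 0.0503), and Kcna1, at 0.953 and 0 FPKM in YFP and 4.30 and 2.21 in DEK, did not pass (adjusted p = 0.0700). Of 17 mature myofibre markers 1 rose and 1 fell, and 4 rose and 1 fell adjusted over the list alone (median 0.10, turning to -0.02 after quantile normalization, camera adjusted p = 0.714). The fast fibre gene Actn3 rose from 28.8 ± 1.88 to 153 ± 6.62 FPKM and the giant sarcomere protein gene Ttn fell from 19.7 ± 1.86 to 3.58 ± 0.339 FPKM; Tnnc2 and Tnnt1 had log2 fold changes of 2.23 and 0.74 (adjusted p = 0.0577 and 0.0638). With the libraries left out in turn limma called 1, 1, 0 and 1 myofibre markers higher and 1, 0, 0 and 0 lower, with 4, 3, 4 and 7 and with 2, 1, 3 and 1 at an unadjusted p under 0.05. Refiltered, the numbers were 1, 1, 1 and 5 higher and 1, 1, 2 and 1 lower. Without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, limma called 1, 1, 0 and 1 leukocyte, 0, 0, 0 and 2 erythroid and 0, 0, 0 and 1 Schwann cell genes higher, with 3, 6, 3 and 2, with 3, 2, 5 and 3 and with 6, 4, 4 and 6 at an unadjusted p under 0.05. With an added value of 0.1 or 5 the medians were 3.07 and 1.18 for leukocyte, 5.18 and 2.21 for erythroid and 1.68 and 0.48 for Schwann cell markers. The Schwann list was lost at 5 FPKM or more (0.109, range over alternatives 0.000106 to 0.626). With a DEK library left out the refiltered setting kept 4 or 3 of 7 leukocyte and 2 or 1 of 5 erythroid members and tests neither list.

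**Figure D2:**
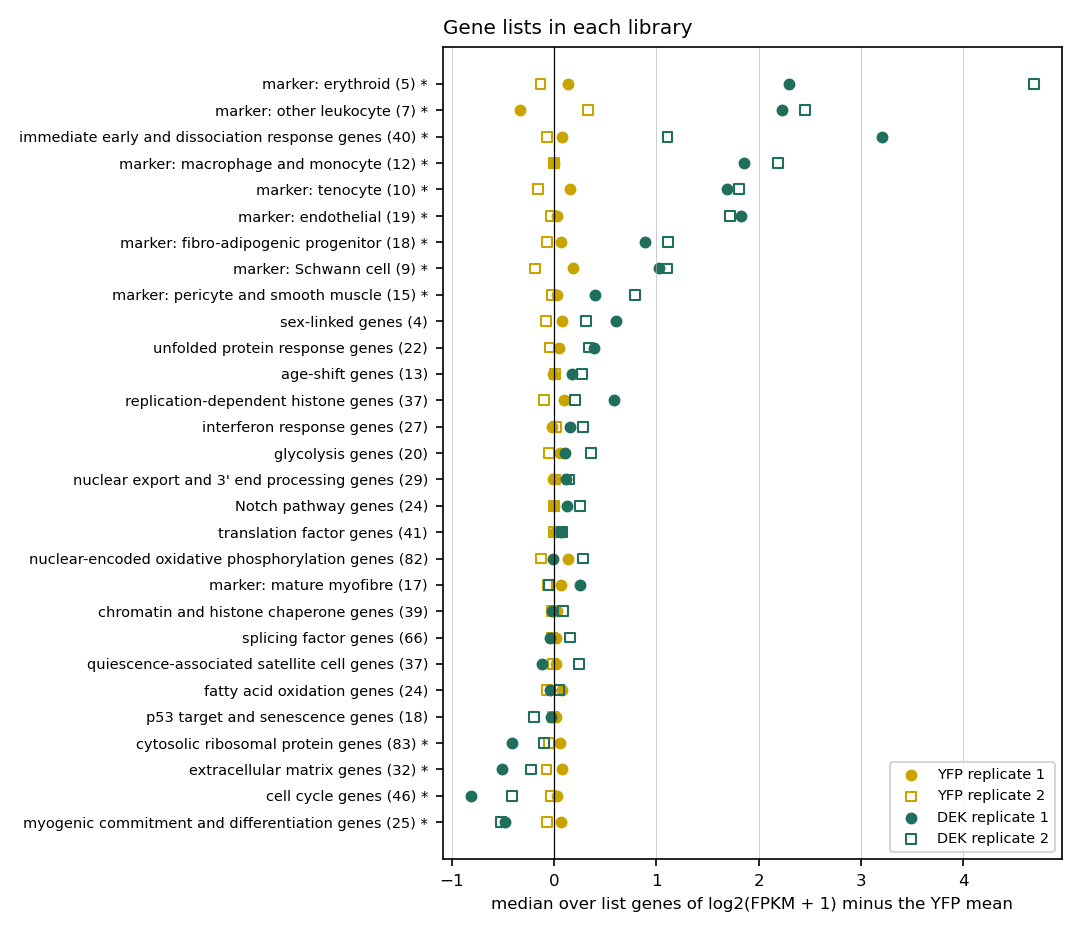
The x axis is the median over each list's genes of log2(FPKM + 1) minus the YFP mean, with a point for each of the 4 libraries; the y axis names the lists with their tested genes in parentheses, and an asterisk marks those past camera at an adjusted p under 0.05. The dissociation response list stands at 3.20 in DEK replicate 1 and 1.11 in DEK replicate 2, and the endothelial list at 1.82 and 1.72.

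Of 32 extracellular matrix genes 9 fell and 0 rose by limma, against 3 higher at an unadjusted p under 0.05, and 13 fell and 1 rose adjusted over the list alone (median -0.26, camera adjusted p = 0.000113; adjusted p = 0.650 with an estimated correlation). Against the YFP mean the median was -0.51 in DEK replicate 1, and so without DEK replicate 2, and -0.23 in DEK replicate 2. The matrix glycoprotein Sparc went from 500.06 ± 41.4 to 201 ± 37.5 FPKM (log2 fold change -1.32, SE 0.18, adjusted p = 0.0160). The collagen genes Col3a1, Col4a2 and Col5a3 had log2 fold changes of -1.16 (SE 0.20), -1.33 (SE 0.21) and -1.10 (SE 0.17). In the same libraries the fibro-adipogenic progenitor markers, which share Col1a1, Col1a2 and Col3a1 with this list, had a median of 1.07. Matrix genes called lower by limma numbered 0, 0, 0 and 1 without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, with 11, 11, 13 and 17 at an unadjusted p under 0.05; refiltered, 3 were called without DEK replicate 1 and 11 without DEK replicate 2.

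Signalling, age and sex lists did not pass camera. In the Notch pathway, which keeps satellite cells quiescent, 1 of 24 rose and 0 fell, with 2 lower at an unadjusted p under 0.05, and 2 rose and 1 fell adjusted over the list alone (median 0.20, camera adjusted p = 0.355). The glycosyltransferase Lfng, a modifier of Notch, was at 0 and 0.0648 FPKM in YFP and 1.72 and 1.19 in DEK (adjusted p = 0.0359), while Hey1, Maml3 and Hes6 had log2 fold changes of 0.64, -0.74 and 0.45 that did not pass (adjusted p = 0.0558, 0.0615 and 0.0952). Of 27 interferon response genes 0 passed limma over all genes and 0 adjusted over the list alone, with 9 higher and 1 lower at an unadjusted p under 0.05 (median 0.32, camera adjusted p = 0.0585). That median fell to 0.15 without DEK replicate 2. Gbp2, Ifih1, H2-D1 and Rsad2 had log2 fold changes of 0.76, 0.62, 0.57 and 0.72, all with adjusted p of 0.0615 or more. The interferon list passed camera without YFP replicate 2 (adjusted p = 0.0394) and without DEK replicate 2 (0.0333), in a range over alternatives of 0.0333 to 0.626, and refiltered without DEK replicate 2 limma called 3 members higher. Of 13 genes reported to shift with age 1 rose, and 2 rose and 1 fell adjusted over the list alone (median 0.34, or 0.18 without DEK replicate 2, camera adjusted p = 0.320 with all libraries). Igfbp5, which binds insulin-like growth factors, rose from 294 ± 61.3 to 848 ± 131 FPKM (log2 fold change 1.53, SE 0.20, adjusted p = 0.0157), while Spry1, Jak2 and Socs1 had log2 fold changes of 0.60, -0.68 and 2.33 that did not pass (adjusted p = 0.0667, 0.0810 and 0.105). Of 4 sex-linked genes 0 passed limma over all genes and 1 rose adjusted over the list alone, with 2 higher at an unadjusted p under 0.05 (median 0.44, camera adjusted p = 0.0802). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were expressed in all 4 libraries, with log2 fold changes of 0.57, 0.32, 0.52 and 0.35. That list passed camera without DEK replicate 2 (adjusted p = 0.0333, range over alternatives 0.0333 to 0.650). With any library left out limma called 0 Notch genes on the same genes, with 3, 3, 4 and 6 higher at an unadjusted p under 0.05. The Lfng call was lost each time, and Lfng missed the filter when refiltered without a DEK library. Age-shift genes called higher by limma numbered 0, 0, 0 and 2 without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, with 2, 2, 4 and 5 at an unadjusted p under 0.05. Refiltered they numbered 0, 0, 1 and 3, with Igfbp5 as the 1 without DEK replicate 1.

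Among genes of RNA processing and chromatin, few passed. In splicing factors 4 of 66 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone (median 0.06, camera adjusted p = 0.714, with the median at -0.08 with Rn45s removed and -0.03 after quantile normalization). The splicing regulators Srsf6 and Srsf5 rose with log2 fold changes of 1.01 (SE 0.14) and 0.88 (SE 0.18), and Luc7l3 fell with -0.80 (SE 0.13). In chromatin and histone chaperone genes, a group that shares Dek's setting, 1 of 39 fell and 0 rose over all genes, and 0 passed adjusted over the list alone, with 5 higher and 5 lower at an unadjusted p under 0.05. The median was 0.07, the mean 0.03 and the direction of the test down (camera adjusted p = 0.714), with the median at -0.10 with Rn45s removed and -0.03 after quantile normalization. The histone chaperone subunit Chaf1b fell from 4.55 ± 0.00369 to 1.503 ± 0.479 FPKM (log2 fold change -1.16, SE 0.22), while Ezh2, Hira and H3f3b had -0.81, -0.77 and 1.41 and did not pass (adjusted p = 0.0591, 0.0647 and 0.0794). In nuclear export and 3' end processing genes 0 of 29 passed limma over all genes or adjusted over the list alone, with 6 higher and 1 lower at an unadjusted p under 0.05 (median 0.21, camera adjusted p = 0.597); Xpo1, Dis3, Upf1 and Cpsf3 had log2 fold changes of 0.54, 0.62, -0.96 and 0.49. Of 37 replication-dependent histone genes 6 rose and 2 fell, and 13 rose and 5 fell adjusted over the list alone (median 0.32, camera adjusted p = 0.252). Hist1h3f, Hist1h2bj and Hist1h2be rose with log2 fold changes of 2.68 (SE 0.28), 2.19 (SE 0.27) and 1.72 (SE 0.24). The histone list passed camera without DEK replicate 2 (adjusted p = 0.00516, range over alternatives 0.00516 to 0.870). With each library left out in turn limma called 0 splicing factors, with 8, 4, 7 and 6 higher at an unadjusted p under 0.05 without YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2. Refiltered, 2 splicing factors rose without DEK replicate 1, and 4 rose and 1 fell without DEK replicate 2. Histone genes called higher by limma numbered 0, 0, 0 and 6 in the same order, with 15, 9, 12 and 16 at an unadjusted p under 0.05, and 1, 0, 0 and 6 refiltered, with 14, 10, 4 and 9. Chromatin genes called by limma numbered 0 without YFP replicate 1, YFP replicate 2 and DEK replicate 1, with 0, 0 and 6 higher and 3, 4 and 5 lower at an unadjusted p under 0.05. Without DEK replicate 2, 2 chromatin genes were called higher, and refiltered 4 higher and 1 lower, with 1 higher without DEK replicate 1. The direction of the calls rests on the libraries used. In nuclear export genes 1 rose refiltered without DEK replicate 2.

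In translation factors 1 of 41 rose and 0 fell over all genes, and 0 passed adjusted over the list alone, with 4 higher and 3 lower at an unadjusted p under 0.05 (median 0.15, camera adjusted p = 0.458). That median was 0.051 without YFP replicate 2 and 0.065 without DEK replicate 2. The RNA helicase Eif4a1 rose from 147 ± 0.0734 to 258 ± 33.2 FPKM (log2 fold change 0.80, SE 0.15, adjusted p = 0.0346), while Eif5a, Eif2b3 and Eif4ebp1 had 0.58, 0.65 and -0.77 and did not pass. On the same genes limma called 0 translation factors with any library left out, with 4, 2, 6 and 8 higher at an unadjusted p under 0.05; refiltered, 3 rose and 1 fell without DEK replicate 2. The list of 83 cytosolic ribosomal protein genes passed camera downward at the preset correlation (median -0.25, camera adjusted p = 3.12e-06; adjusted p = 0.716 with an estimated correlation), and 0 passed limma over all genes or adjusted over the list alone, with 1 higher and 7 lower at an unadjusted p under 0.05. Rpsa, Rps12 and Rps20 had log2 fold changes of -0.75, -0.57 and -0.47 and Rps27 had 0.44, with adjusted p of 0.0534 for Rpsa and 0.0958, 0.135 and 0.136 for the others. Against the YFP mean the ribosomal list median was -0.41 in DEK replicate 1 and -0.10 in DEK replicate 2, and it was -0.40 with Rn45s removed. Leaving out YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, limma called 0 ribosomal genes each time, with 1, 1, 2 and 44 lower at an unadjusted p under 0.05. Refiltered, it called 6 lower without DEK replicate 2, with 52 at an unadjusted p under 0.05.

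Energy metabolism genes did not pass camera as lists. In glycolysis 1 of 20 rose and 0 fell, with 6 higher and 0 lower at an unadjusted p under 0.05 by limma, and 1 rose adjusted over the list alone (median 0.28, camera adjusted p = 0.144). Without DEK replicate 2 that median was 0.11. The pyruvate kinase gene Pkm rose from 229 ± 13.96 to 386 ± 7.92 FPKM (log2 fold change 0.75, SE 0.13, adjusted p = 0.0323), while Tpi1, Pdk1 and Slc2a1 had 0.55, 0.65 and 1.03 and did not pass. In fatty acid oxidation 2 of 24 rose and 2 fell, and 4 rose and 4 fell adjusted over the list alone. The median was 0.01, the mean 0.21 and the direction of the test down (camera adjusted p = 0.714), with the median at -0.10 with Rn45s removed, -0.08 after quantile normalization and -0.02 after TMM scaling. The members that rose were Fabp4, also in the endothelial list, and the fatty acid transporter Cd36, which went from 0.180 ± 0.232 to 13.3 ± 7.197 FPKM (log2 fold change 3.52, SE 0.38). Cpt1a, which carries fatty acids into mitochondria, and the dehydrogenase Acadl fell with log2 fold changes of -1.02 (SE 0.18) and -0.85 (SE 0.17). In nuclear-encoded oxidative phosphorylation genes 3 of 82 rose and 1 fell, and 2 rose and 1 fell adjusted over the list alone (median 0.14, camera adjusted p = 0.119). Ndufa4l2 was at 0.0989 and 0 FPKM in YFP and 8.02 and 8.30 in DEK (adjusted p = 0.00336), Cox4i2 and Ndufs8 rose with log2 fold changes of 1.34 (SE 0.24) and 0.64 (SE 0.14), and Cox8b fell with -1.05 (SE 0.18). The glycolysis list passed camera without DEK replicate 1 (adjusted p = 0.0318, range over alternatives 0.0318 to 0.716), and the oxidative phosphorylation list without YFP replicate 1 (0.0124) and DEK replicate 1 (0.00139, range 0.000813 to 0.994). Mitochondrially encoded genes had no symbol in the table, so that list held 0 genes. With any library left out limma called 0 glycolysis genes on the same genes, with 5, 3, 5 and 5 higher at an unadjusted p under 0.05, and 0 fatty acid oxidation genes lower, with 5, 5, 4 and 4. The Pkm, Cpt1a and Acadl calls were lost each time. In the order YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2, limma called 1, 1, 0 and 2 fatty acid oxidation and 1, 1, 0 and 1 oxidative phosphorylation genes higher, with 4 each time and with 14, 5, 9 and 6 at an unadjusted p under 0.05. Refiltered without DEK replicate 1, Pkm and Fabp4 were called higher and Cpt1a lower. Refiltered without DEK replicate 2, Pkm and Fabp4 were called higher and Cpt1a and Acadl lower, with glycolysis calls in both directions.

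**Figure D3:**
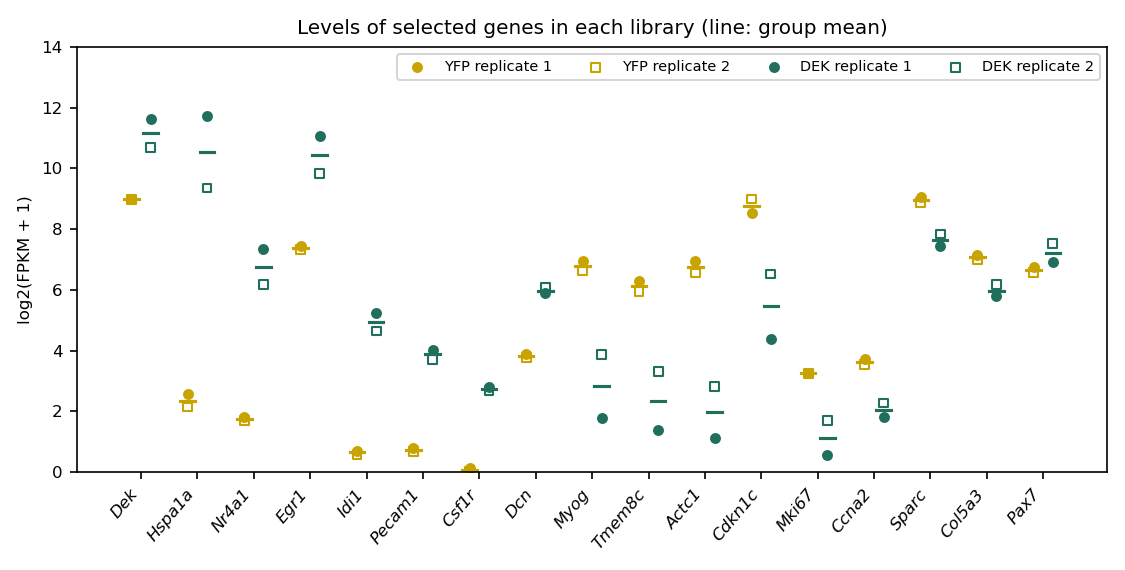
The y axis is log2(FPKM + 1) of each gene named on the x axis, with a point for each of the 2 YFP and 2 DEK libraries and a line at the group mean. For Dek both DEK points lie above both YFP points, with a log2 fold change of 2.17.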

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

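The alternatives chosen only after the data were seen were the removal of Rn45s and the low filter applied to the 3 remaining libraries when 1 was left out. Which genes pass rests on all 4 libraries. With a library left out, over both ways of filtering, the number of genes changed ran from 0 to 780 by limma, the higher genes from 0 to 371 and the lower genes from 0 to 409; at the 0, without DEK replicate 1, 2215 genes had an unadjusted p under 0.05. The log2 fold change of Dek then ran from 1.69 to 2.65. With the replicate number as a block (replicate block) 618 genes changed, 235 of them lower, and 561 calls were shared with the unblocked fit; the labels do not say what the numbers mark. With no low filter 293 genes changed, 216 higher and 77 lower, and Dek kept its log2 fold change of 2.17 with an adjusted p of 0.0863, where 18329 genes were tested. At 2-fold or more 260 genes were lower, and at an adjusted p under 0.1, 2096 changed, 1237 higher and 859 lower. Other settings gave 732 genes (added value 0.1), 916 (added value 5), 771 (5 FPKM), 1089 (TMM), 1038 (quantile), 832 (no trend), 1062 (robust) and 990 (Rn45s removed), sharing 729, 890, 688, 919, 847, 764, 930 and 810 calls with the 948. Apart from the smaller designs and the changed thresholds or gene numbers, the cause was not tested.

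Of the lists, 0 passed camera with an estimated correlation, with 1 at an unadjusted p under 0.05, and 2 passed fry, against 13; 18 lay outside the central 95% of random lists. For the macrophage list, whose estimated correlation lay below the preset one, a higher correlation is argued against as the cause. The estimated setting also tests on fewer degrees of freedom, which raises p by itself. For the other lists that passed, the parts of both effects were not separated. For fry and the random lists the cause was not tested. The lists that changed sign had medians near 0. With Rn45s removed, medians were -0.112 for quiescence, -0.0788 for splicing, -0.0965 for fatty acid oxidation and -0.0964 for chromatin genes. After quantile normalization they were -0.0987 for quiescence, -0.0310 for splicing, -0.0772 for fatty acid oxidation, -0.0334 for chromatin and -0.0154 for mature myofibre genes. After TMM scaling quiescence stood at -0.0114 and fatty acid oxidation at -0.0151, and the latter stood at -0.000311 with an added value of 0.1. With a library left out, medians ran from -0.116 to 0.242 for quiescence, -0.0365 to 0.155 for splicing, -0.0750 to 0.116 for fatty acid oxidation, -0.0209 to 0.0857 for chromatin, -0.160 to 0.396 for mature myofibre, -0.0135 to 0.280 for oxidative phosphorylation and -0.0548 to 0.857 for histone genes. No sign changed among the 13 lists that passed. Over all settings, 454 list medians kept sign and side of the threshold, 32 changed sign, 19 newly passed and 17 no longer passed. For named genes, 1794 values kept sign and side, 39 newly passed and 503 no longer passed. Unknown depth limits what can be said of genes near 0.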

Other observations

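The tests on the endothelial, macrophage and dissociation lists were chosen only after their results were seen, and the cholesterol, glucocorticoid and clock sets were chosen after the comparison of DEK with YFP had been seen but tested with bounds written before the sets' own values were known.

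Of the cholesterol synthesis genes, Idi1, Sqle and Msmo1 were among the 4 genes that drew attention to the set, with log2 fold changes of 4.31 (SE 0.25), 3.12 (SE 0.29) and 3.06 (SE 0.21). Leaving those 4 genes out, 18 of 20 other measured members had positive values, 10 rose and 0 fell by limma, and 16 rose adjusted over the list alone. Their median log2 fold change was 1.12 (camera p = 2.81e-10; p = 0.107 with an estimated correlation). Hsd17b7, an enzyme of the late pathway, went from 4.21 and 5.21 FPKM in YFP to 38.7 and 42.5 FPKM in DEK. Cyp51, Fdps, Fdft1 and Lss, further enzymes of the pathway, had log2 fold changes of 2.67 (SE 0.24), 2.65 (SE 0.23), 2.47 (SE 0.22) and 2.06 (SE 0.15), and Insig1, which the pathway's own transcription factor induces, had 2.45 (SE 0.22).

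Core clock genes lay on opposite sides of 0 in 2 arms. All 10 measured members of the arm with Dbp and the Per genes had negative values, 5 fell and 0 rose by limma, and the median was -0.86 (camera p = 1.35e-06; p = 0.157 with an estimated correlation). Dbp went from 108 and 118 FPKM in YFP to 24.2 and 46.0 FPKM in DEK, and Per3 and Nr1d1 had log2 fold changes of -1.16 (SE 0.19) and -1.10 (SE 0.24). In the opposite arm all 5 members had positive values and 2 rose, Arntl with 2.55 (SE 0.30) and Npas2 with 1.24 (SE 0.16), around a median of 1.24 (camera p = 0.00709, or 0.111 with an estimated correlation). Cry1 in this arm (log2 fold change 0.11) and Ciart in the Dbp and Per arm (-0.07) overlapped between the groups. Clock stood at 45.3 and 8.97 FPKM in YFP and at 57.0 and 46.2 FPKM in DEK, so its value rests on YFP replicate 2. With YFP replicate 1, YFP replicate 2, DEK replicate 1 and DEK replicate 2 left out, limma called 6, 6, 0 and 3 cholesterol genes higher, with 15, 13, 14 and 11 at an unadjusted p under 0.05, and 8, 6, 11 and 9 with the low filter on the 3 remaining libraries. In the Dbp and Per arm limma called 0, 0, 0 and 2 lower, with 8, 7, 7 and 8 at an unadjusted p under 0.05, and 0, 0, 2 and 5 with that filter. In the Arntl arm limma called 1, 0, 0 and 0 higher, with 3, 2, 2 and 3 at an unadjusted p under 0.05, and 2, 0, 1 and 3 with that filter.

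Endothelial and macrophage markers were higher in both DEK libraries. A share of Rn45s that differs between groups is argued against as the whole cause by its size. Its removal moved the median log2 fold change of all genes only from 0.05 to -0.07, so it could not have undone an endothelial median of 1.73. With Rn45s removed that median stayed at 1.78, an outcome largely fixed in advance. A lower share of satellite cells that raises every other type alike, myofibres included, would raise both endothelial and myofibre markers. It need not move them by the same amount, since the change of a gene near 0 in YFP rests on its level in its own cell type. Over members under 1 FPKM in both YFP libraries the endothelial median exceeded that of myofibre markers by 1.79 (1.501 to 1.997 with a library left out). In these libraries the lists thus did not rise alike, which cannot decide for or against a lower share of satellite cells. The two-sided permutation p of 0.00071 shuffled list labels over genes, which are not independent, after the medians of both lists were known. It does not measure the spread between libraries, so no conclusion is drawn from it. Cells or RNA of endothelial cells and macrophages in the DEK libraries cannot be told apart from expression of these genes by the satellite cells themselves, with more Dek or at another age. Of the 29 members of both lists under 1 FPKM in both YFP libraries, 96.6% had both DEK values above both YFP values, but the lists were already known to be higher, so that share decides nothing. The rise was not particular to these lists. The share was 100% in pericyte, 87.5% in erythroid, 85.7% in progenitor and 83.3% in Schwann cell markers. In tenocyte, other leukocyte and myofibre markers it was 80%, 69.2% and 25%. Over all such genes above 0 in a library it was 36.3%. These lists held 3 to 13 such members each. A gate on the reporter would remove such cells, but the labels give no gate, and a rise limited to mononuclear cell types stays open.

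The immediate early and dissociation list was higher in DEK, most so in DEK replicate 1. A response in DEK replicate 1 alone is argued against, since DEK replicate 2 lay above the YFP mean by a median of 1.11, where the YFP libraries differed by a median of 0.21. Handling that differed between libraries cannot be told apart from a response that grows with Dek: DEK replicate 1 exceeded DEK replicate 2 by a median of 1.76 over the list, and Dek itself was higher in the same library by 0.96 on the log2 scale, in a value that is not known to count the transgene in full. With 2 DEK libraries the order of the list and of Dek matches by chance too often to decide. Since perfusion came before digestion, handling here means steps up to fixation, or digestion if fixation was incomplete. Age and reporter go with the group and stay open, untested.

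The glucocorticoid-induced genes Fkbp5 and Tsc22d3 were lower in DEK, with log2 fold changes of -2.63 (SE 0.18) and -1.87 (SE 0.15). Without these and Angptl4, which fell with -2.04 (SE 0.29), the other 27 members had a median of -0.43 (18 negative, 5 lower and 2 higher by limma, camera p = 0.00499; p = 0.0877 with an estimated correlation). The 2 called higher were Errfi1 with 1.301 (SE 0.13) and Sult1a1 with 1.18 (SE 0.20). Per1, whose value is the median of these members, also belongs to the Dbp and Per arm, so these sets are not fully separate. With the libraries left out in the same order limma called 0, 0, 0 and 1 lower and 0, 0, 0 and 2 higher, with 10, 7, 10 and 9 lower and 2, 4, 3 and 6 higher at an unadjusted p under 0.05. With the low filter on the 3 remaining libraries it called 1, 0, 5 and 5 lower and 0, 0, 2 and 5 higher, so lower expression of the set as a whole stays open. A difference in clock phase is a candidate explanation, since glucocorticoids follow the day: the median of the Dbp and Per arm minus that of the Arntl arm was -2.09, with the arms on opposite sides of 0. The labels give no time of collection. Effects of Dek, age or reporter on either set remain untested alternatives.

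The following genes were chosen after their values were seen. The overlapping genes Lrch4 and Gm20605 moved in opposite directions, with log2 fold changes of 3.86 (SE 0.18, adjusted p = 0.00289) and -2.49 (SE 0.31, adjusted p = 0.0141). Reads shared between such genes make both changes uncertain. The value listed for the mitochondrial leucyl-tRNA synthetase gene Lars2 fell from 2094 ± 149 to 946 ± 24.6 FPKM (log2 fold change -1.14, adjusted p = 0.0170). Rn45s had a log2 fold change of -1.34 and did not pass (adjusted p = 0.0603). The change of Lars2 lay close to that of Rn45s, and whether its value comes from its own messenger RNA was not tested. The cell cycle kinase gene Wee1 fell with -2.16 (SE 0.18, adjusted p = 0.00478).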
